A study of Rattus norvegicus with 8 samples.

How the data were processed

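Nascent RNA was measured by BrU-seq, in which living cells take up bromouridine (BrU), an RNA base analogue, for a short time and the labelled, newly made RNA is captured with an antibody and sequenced. The cells were primary co-cultures of hippocampal and cortical neurons from newborn Sprague Dawley rats. Per the labels' protocols, cultures received vehicle (water) or 1 µM tetrodotoxin (TTX, a blocker of voltage-gated sodium channels that silences action potentials) for 24 h from day 14 in vitro. The drug was then washed out for 48 h, and vehicle or TTX was given again on day 17 for 4 h, with 2 mM BrU present for the last 30 min. The 4 groups are named by the first and the second treatment, H for vehicle and T for TTX: HH, HT, TH and TT, with 2 libraries each. Groups and replicate numbers were taken from the sample titles.

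The deposited table holds whole-number read counts for 16871 gene symbols, not normalized. Per the submitters' processing notes, FastQC, Bowtie2, TopHat2 and featureCounts were used with rat genome build rn6; their versions, the gene annotation, the strand setting, whether intronic reads were counted and how the genes in the deposited table were selected are not given in the sources used here. Nascent RNA is largely unspliced, so a setting that left introns out would lower the counts of genes with long introns, and reads of overlapping or antisense genes may not be told apart. The 8 columns used were matched to samples by the number that opens each sample's description; 2 further columns matched no sample and were not used. Gene positions were not analysed here. The labels give no batch or date, so no comparison was made within batches.

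The total count per library lay between 3489176 and 4959887. Of the 16871 genes, 1954 had no count in any of the 8 libraries, and 11372 (67.4%) passed edgeR's expression filter and were tested. Pearson correlations of log2 CPM (counts scaled to the normalized library total, prior count of 2) within groups ran from 0.974 to 0.987, and in each group the replicates differed by more than sampling noise in a chi-square test, so that no library was counted as a repeat of another. Each library correlated most highly with a library of another group, up to 0.988 between TH replicate 2 and TT replicate 2. Replicates were thus not the closest pairs. The common biological coefficient of variation was 0.128. Nothing in the labels says whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

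Counts were analysed in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values (TMM) scaling, 1 model of the 4 group means with 4 residual degrees of freedom, and the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 and no minimum fold. Log2 fold changes are given with a standard error, n = 2 libraries per group. It was worked back from the test, as the absolute log2 change over the square root of the F statistic. It rests on the spread within all 4 groups, moderated across genes, and not on the groups compared alone. A wide gap between the replicates of 1 group can thus widen it in every comparison. The comparisons were HT against HH and TT against TH (the second TTX, without and with a history of TTX), TH against HH and TT against HT (the history, without and with the second TTX), the interaction, and the effects of each treatment averaged over the other. Gene lists, 27 in number and written before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 27 lists within each comparison, then with an estimated correlation and with fry. Exact permutation tests, two-sided, compared per-library list levels (the mean log2 CPM of a list's members) over the 70 assignments of 8 libraries into 4 and 4, the smallest possible p being 0.0286. These assignments do not hold the other treatment fixed. Permuting only within its levels allows fewer assignments, so the smallest possible p would be larger. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

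Genes named in the text followed a rule fixed before the data were examined: in each of the 4 pairwise comparisons and the interaction, the 12 largest rises and falls among genes past the threshold, or, where none passed, the 5 genes of smallest p, placeholder symbols left out; up to 4 members of each list by smallest p; and Fos, Npas4, Arc, Bdnf, Homer1, Nptx2, Gria1 and Gria2 in every comparison. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

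The edgeR step was tested on simulated counts for the 11372 genes, with 200 genes changed, in 10 simulations. For HT against HH it recovered 64.8% of genes changed 2-fold and 93.6% of those changed 4-fold, and 8.49% of its calls were false, above the nominal 5%. For the second TTX averaged over history the shares were 85.0%, 98.2% and 7.52%. With the cholesterol list lowered by 0.5 on the log2 scale in simulated HT libraries, camera called it with the preset correlation and with an estimated correlation (adjusted p = 0.00774 with an estimated correlation), and with the preset correlation also called 2 of the 26 lists left unchanged. This list step was a single run in which genes were drawn independently of each other. It does not show how either setting fares when the genes of a list vary together.

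The alternatives tried were DESeq2 1.42.0, limma-voom, scaling by median of ratios, by upper quartile or by library size only, no low-count filter, a filter of at least 1 CPM in 4 libraries, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Leaving out HH replicate 1 and HT replicate 1 together was added after the data were seen. A pseudocount alternative planned for normalized values did not apply to counts. DESeq2 gave no adjusted p for 2646 genes in the averaged second-TTX comparison, and these stayed out of its calls.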

Results

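Newly made RNA was counted in 8 libraries of cultured rat neurons that were silenced or not with TTX for 24 h and, after a washout of 48 h, silenced or not for 4 h. The design asks whether an earlier period of silence alters the transcription that follows a later one. Totals ran from 3489176 counts in TH replicate 1 to 4959887 in TH replicate 2. E2f1, named after its values were seen, held the largest share in each library, from 0.853% to 1.43%. No single gene of the 11372 tested passed the adjusted threshold in any of the 7 comparisons (edgeR). Gene groups are therefore described first, and single genes are named as not passing.

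Genes that neurons switch on when they fire, such as Fos, Npas4 and Arc, were highest in 1 of the 8 libraries. In HH replicate 1, Fos stood at 37.0 CPM, Npas4 at 53.0, Arc at 41.6, Bdnf, a secreted neurotrophin, at 122 and the synaptic scaffold gene Homer1 at 787. In HH replicate 2, given the same treatments, the values were 5.74, 3.91, 7.04, 20.1 and 297 CPM. The 4 libraries given the second TTX ranged from 6.46 to 11.6 CPM for Fos and from 12.1 to 36.0 CPM for Bdnf. Of the rapid activity-response genes, 16 of 22 had their highest value in HH replicate 1, as did 30 of 36 later activity-response genes. HT replicate 1, although given the second TTX, was the next highest. Its median log2 position against the others was 0.251 for the rapid, 0.259 for the later and 0.639 for the ERK pathway feedback genes. HH replicate 1 stood at 0.831, 0.801 and 0.922. The labels do not say whether HH replicate 1 and HT replicate 1 came from 1 culture. The HH replicates differed by over 2-fold in 546 tested genes, against 281 in HT, 180 in TH and 155 in TT. The first principal component, with 33.0% of the variance, placed HH replicate 1 at -37.7 and HT replicate 1 at -12.7, with the other 6 libraries between 7.06 and 12.5.

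**Figure D1:**
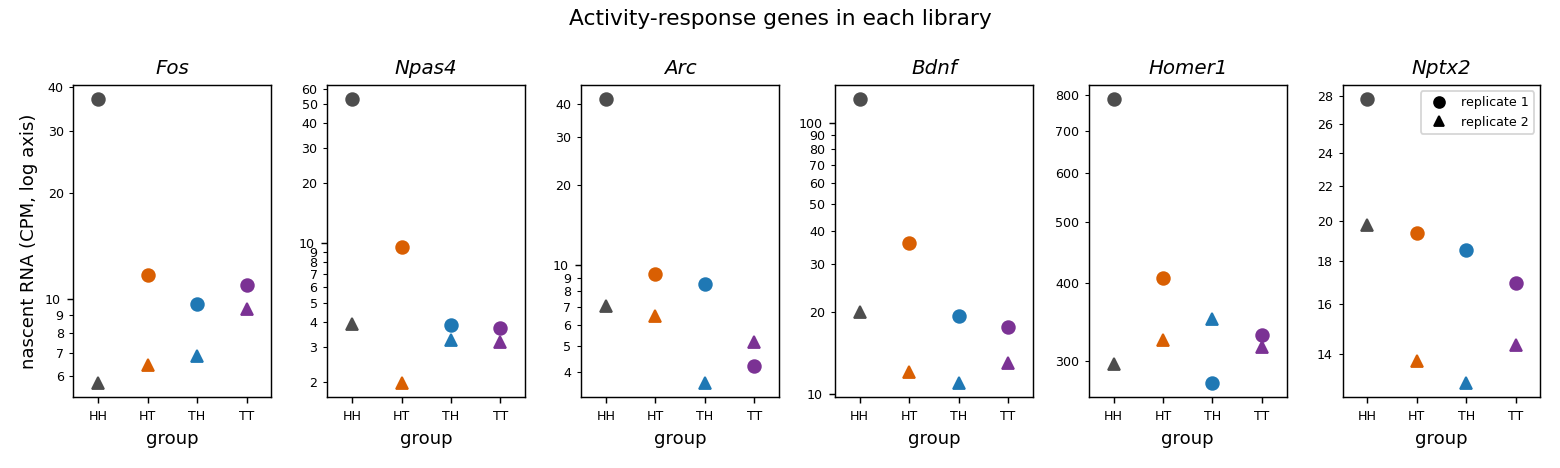
Nascent RNA of 6 activity-response genes in each of the 8 libraries, in CPM on a log axis that differs between panels, by group (HH, HT, TH, TT), with circles for replicate 1 and triangles for replicate 2. HH replicate 1 is the highest library for every gene shown, with Npas4 at 53.0 CPM against 3.91 in HH replicate 2.

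The first comparison asks what 4 h of TTX did to cultures with no earlier silencing (HT against HH). Genes of cholesterol synthesis and uptake fell as a group: all 21 tested members lay below 0, with a median log2 change of -0.53 (camera adjusted p = 1.60e-16, adjusted p = 0.225 with an estimated correlation). Hmgcs1, which encodes an early enzyme of the mevalonate pathway, stood at -0.70 ± 0.16 (log2 fold change ± SE, n = 2 per group), Msmo1 at -0.64 ± 0.18 and Idi1 at -0.88 ± 0.25. Markers of the oligodendrocyte lineage rose as a group, with 15 of 16 above 0 and a median of 0.55 (camera adjusted p = 7.05e-11, adjusted p = 0.222 with an estimated correlation). Among them were the progenitor genes Cspg4 (0.73 ± 0.12) and Pdgfra (0.50 ± 0.15), and Gpr17 (1.00 ± 0.33). Markers of dividing cells rose too, with 16 of 18 above 0 and a median of 0.70 (camera adjusted p = 3.86e-11, adjusted p = 0.222 with an estimated correlation). These included Rrm2 (1.20 ± 0.27), Cdk1 (0.99 ± 0.23), Cenpf (0.84 ± 0.20) and Top2a (0.73 ± 0.21).

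Astrocyte markers moved the same way by less (median 0.16, camera adjusted p = 0.00277, adjusted p = 0.222 with an estimated correlation), with Gfap at 0.42 ± 0.17 and Aqp4 at 0.30 ± 0.14. Excitatory neuron markers had a median of 0.0046 and passed no test (camera adjusted p = 0.892). Inhibitory neuron markers fell (median -0.36, camera adjusted p = 0.000113, adjusted p = 0.225 with an estimated correlation), with the GABA-synthesis genes Gad1 at -0.75 ± 0.20 and Gad2 at -0.61 ± 0.17. The later activity-response genes fell (median -0.49, camera adjusted p = 1.58e-07, adjusted p = 0.393 with an estimated correlation), with Pcsk1 at -0.99 ± 0.37. So did the rapid ones (median -0.40, camera adjusted p = 0.00116, adjusted p = 0.513 with an estimated correlation), with Egr2 at -1.41 ± 0.47. Adjusted over the list alone, 7 proliferating, 6 cholesterol, 5 oligodendrocyte lineage and 2 inhibitory neuron genes passed, against 0 of each over all genes tested. Camera called 16 of the 27 lists at the preset correlation, 3 higher and 13 lower, and none with an estimated correlation (smallest adjusted p = 0.222 with an estimated correlation). The remaining lower lists follow with the median log2 change and, in parentheses, the camera adjusted p and then the adjusted p with an estimated correlation. Neuropeptides and secreted neurotrophic factors stood at -0.47 (1.45e-06, 0.308), cytosolic ribosomal proteins at -0.15 (0.000113, 0.567). Oxidative phosphorylation genes stood at -0.12 (0.000368, 0.542), presynaptic release genes at -0.15 (0.000373, 0.316). NMDA, kainate and metabotropic glutamate receptors stood at -0.18 (0.00236, 0.225), potassium and HCN channels at -0.15 (0.00527, 0.319). GABA receptors and inhibitory synapse genes stood at -0.19 (0.00527, 0.393), voltage-gated sodium channels and partners at -0.18 (0.0201, 0.393). ERK pathway feedback genes stood at -0.20 (0.0340, 0.608). AMPA receptor subunits and partners did not pass (median -0.0097, camera adjusted p = 0.123).

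Of single genes, the smallest p belonged to Cspg4, the mitotic motor gene Kif15 (0.97 ± 0.19), the adrenergic receptor gene Adra1a (-1.02 ± 0.20), Acss1 (0.84 ± 0.16) and Ect2 (0.81 ± 0.17), a regulator of cell division, none of which passed (edgeR adjusted p = 0.519 for each). Genes fixed in advance, Gria1 and Gria2 encoding AMPA receptor subunits, did not pass. Fos stood at -1.19 ± 0.78, Npas4 at -2.24 ± 1.21 and Arc at -1.59 ± 0.81. Bdnf stood at -1.54 ± 0.94, Homer1 at -0.57 ± 0.41 and Nptx2 at -0.51 ± 0.26. Gria1 stood at -0.20 ± 0.18 and Gria2 at -0.25 ± 0.19. Their adjusted p was 0.802 or more (edgeR). At an unadjusted p under 0.05 there were 738 genes, 427 higher and 311 lower, against 568.6 expected by chance. In TT against TH there were 300, in TH against HH 464, in TT against HT 267 and in the interaction 186, all below 568.6. Fits of only the groups compared gave 563 here, 427 in TT against TH, 310 in TH against HH and 489 in TT against HT. The 738 genes thus cannot be read as an excess over chance. DESeq2 and limma-voom also called 0 genes at the adjusted threshold. Without HH replicate 1, the later (adjusted p = 0.775), glutamate receptor (0.344), GABA receptor (0.697), presynaptic (0.0626), sodium channel (0.344), potassium channel (0.239) and inhibitory neuron (0.0663) lists no longer passed and the rapid (0.163) and ERK (0.00686) lists turned direction. Without HT replicate 1, the ribosomal (0.496) list no longer passed. Without HT replicate 2, the rapid (0.129), ERK (0.999), GABA receptor (0.515), presynaptic (0.0681), sodium channel (0.342) and potassium channel (0.515) lists no longer passed. Without HH replicate 1 and HT replicate 1 together, the rapid (0.888), glutamate receptor (0.156), sodium channel (0.0756) and ribosomal (0.470) lists no longer passed and the ERK (0.899) list turned direction. The ERK list passed as higher without HH replicate 1 alone. The fit with both left out, added after the data were seen, sets 1 HT library against 1 HH library, and the spread of each is assumed from TH and TT. It thus does not show how these lists vary between replicates of HH or HT. Under that assumption the lower lists that passed included later (0.01), potassium channel (0.000524), inhibitory neuron (0.0264), GABA receptor (0.0228) and presynaptic (0.00141). Without HH replicate 2, which leaves HH replicate 1 as the lone control, assumed to vary like the other groups, 32 genes passed, all lower, 10 of them rapid, later or ERK list members.

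In cultures silenced before, the second TTX (TT against TH) was followed by the same direction in the same 3 groups. Cholesterol genes fell, with 20 of 21 below 0 and a median of -0.43 (camera adjusted p = 5.05e-16, adjusted p = 0.400 with an estimated correlation). Hmgcs1 stood at -0.62 ± 0.16 and the sterol carrier gene Stard4 at -1.12 ± 0.33. Oligodendrocyte lineage markers rose, 14 of 16 above 0 with a median of 0.50 (camera adjusted p = 2.03e-10, adjusted p = 0.300 with an estimated correlation). They included Enpp6 (0.81 ± 0.19), Gpr17 (0.81 ± 0.28) and Cldn11 (1.24 ± 0.47). TT replicate 2 stood apart in these markers, with a list level of 0.71 against 0.15 in TT replicate 1, and held the highest value of 11 of the 16 members, while the call held without it (adjusted p = 0.0177). Proliferating cell markers rose, 17 of 18 above 0 with a median of 0.39 (camera adjusted p = 1.11e-08, adjusted p = 0.300 with an estimated correlation). Cenpf stood at 0.60 ± 0.19, Mki67 at 0.62 ± 0.23, Top2a at 0.54 ± 0.20 and Cdk1 at 0.50 ± 0.22. The rapid (median -0.070) and later (median -0.044) activity-response genes passed no test here (camera adjusted p = 0.467 and 0.127). Nor did the astrocyte markers (median 0.10, 0.180), with Gfap at 0.38 ± 0.17 and S100b at 0.28 ± 0.15.

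Camera called 7 lists, 2 higher and 5 lower, and none with an estimated correlation (smallest adjusted p = 0.300 with an estimated correlation). The further lower lists follow with median, camera adjusted p and adjusted p with an estimated correlation. Presynaptic release genes stood at -0.072 (0.00489, 0.400), potassium and HCN channels at -0.10 (0.00489, 0.400). Inhibitory neuron markers stood at -0.18 (0.00489, 0.400), neuropeptides and secreted neurotrophic factors at -0.16 (0.00946, 0.496). Adjusted over the list alone, 3 cholesterol genes and 2 oligodendrocyte lineage genes passed. No gene passed over all genes tested (edgeR, smallest adjusted p = 1.00), with 300 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The smallest p belonged to Tdrd5 (2.85 ± 0.56), the chromosome condensation gene Smc4 (0.67 ± 0.16), Ect2 (0.70 ± 0.16), A2m (1.28 ± 0.31) and Fam122b (1.07 ± 0.26). None of the genes fixed in advance passed. Fos stood at 0.31 ± 0.82, Npas4 at -0.032 ± 1.64 and Arc at -0.30 ± 0.98. Bdnf stood at 0.037 ± 1.08, Homer1 at 0.041 ± 0.41 and Nptx2 at 0.0036 ± 0.26. Gria1 stood at -0.099 ± 0.18 and Gria2 at 0.078 ± 0.19. With TH replicate 1 left out, the presynaptic (adjusted p = 0.0703) and inhibitory neuron (0.446) lists no longer passed and the neuropeptide (0.721) list turned direction. With TT replicate 1 left out, the inhibitory neuron (0.0681) list no longer passed. With TT replicate 2 left out, the presynaptic (0.591), potassium channel (0.568) and neuropeptide (0.568) lists no longer passed. The number of lists ran from 4 without TT replicate 2 to 13 without TH replicate 1. Without TH replicate 2 a single gene passed, Pole2, named after its values were seen, which had 4.70 CPM in TH replicate 1 and 978 in TH replicate 2.

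**Figure D2:**
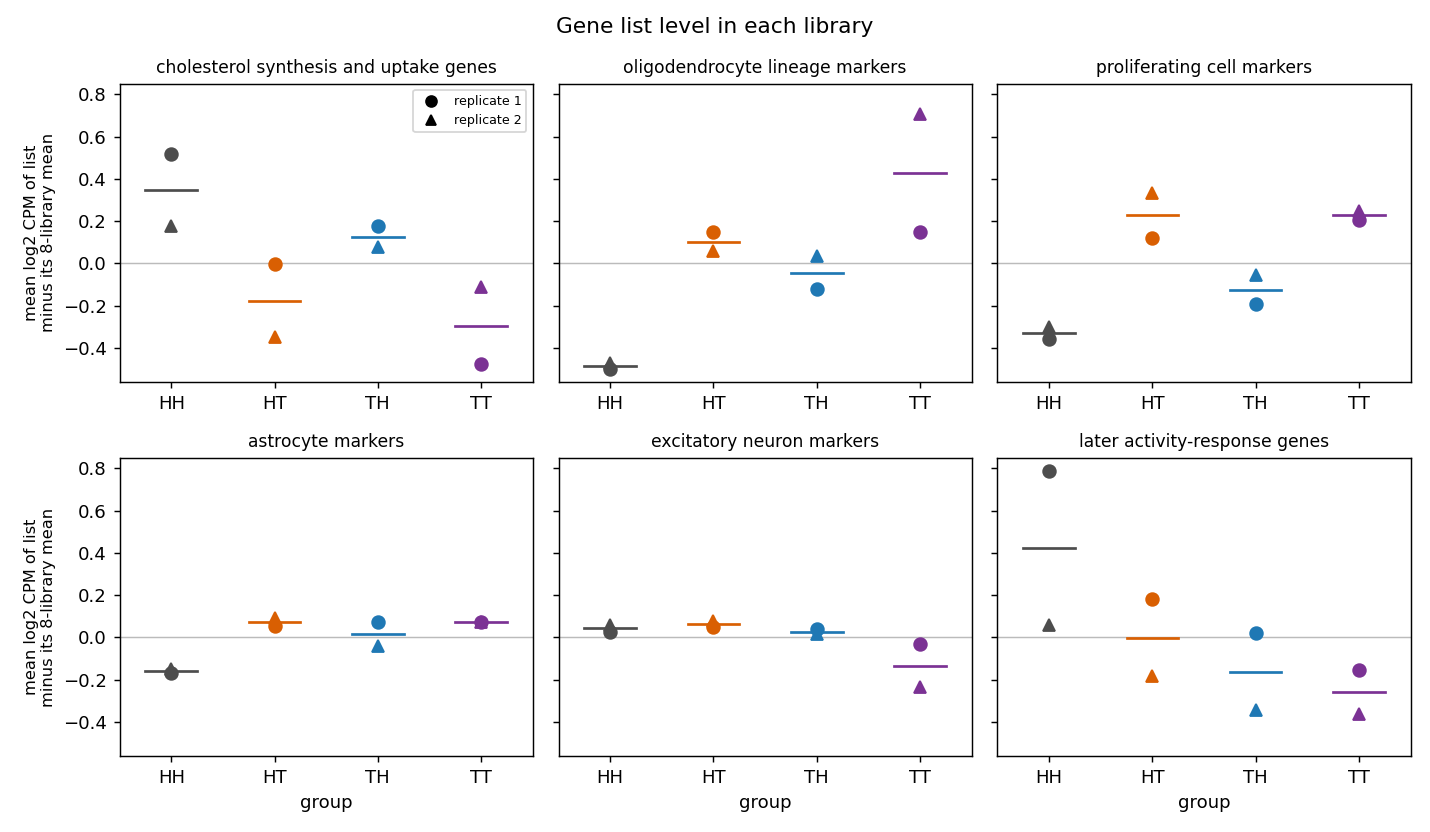
Level of 6 gene lists in each library, as the mean log2 CPM of the tested members minus its mean over the 8 libraries, by group, with circles for replicate 1, triangles for replicate 2 and a bar for the mean of the 2. Cholesterol genes lie between -0.48 and -0.0055 in the 4 libraries given the second TTX and between 0.078 and 0.52 in the 4 given vehicle.

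Averaged over history, cholesterol genes fell as a group after the second TTX, with all 21 below 0 (median -0.46, camera adjusted p = 1.02e-24, adjusted p = 0.171 with an estimated correlation), and 11 passed when adjusted over the list alone, Hmgcs1, Stard4, Msmo1 and Idi1 among them. Oligodendrocyte lineage markers (median 0.55, camera adjusted p = 9.66e-16, adjusted p = 0.147 with an estimated correlation) and proliferating cell markers (median 0.57, camera adjusted p = 3.47e-15, adjusted p = 0.147 with an estimated correlation) rose. In these lists 10 and 10 genes passed when adjusted over the list alone, among them Cspg4, Enpp6, Mki67, Cdk1 and Top2a. The per-library level of each of these 3 lists separated the 4 libraries given the second TTX from the 4 given vehicle. The nearest levels, TTX first, were -0.0055 and 0.078 for cholesterol genes and 0.058 and 0.036 for oligodendrocyte lineage markers. For proliferating cell markers they were 0.12 and -0.055. The means differed by -0.47, 0.53 and 0.45 on the log2 scale (exact permutation p = 0.0286 for each, the smallest possible, and 0.257 adjusted over the 27 lists, history not held fixed). Means ± SD (n = 4) were -0.24 ± 0.22 against 0.24 ± 0.19 for cholesterol genes. They were 0.27 ± 0.30 against -0.27 ± 0.26 for oligodendrocyte lineage markers and 0.23 ± 0.087 against -0.23 ± 0.13 for proliferating cell markers. Without HH replicate 1 the camera adjusted p of the 3 lists at the preset correlation were 5.10e-16, 2.27e-12 and 4.37e-11.

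Camera called 14 lists in this average, 3 higher and 11 lower, and none with an estimated correlation (smallest adjusted p = 0.147 with an estimated correlation). Astrocyte markers were higher (median 0.17, camera adjusted p = 0.00418, adjusted p = 0.171 with an estimated correlation). Other lower lists follow with median, camera adjusted p and adjusted p with an estimated correlation. Neuropeptides and secreted neurotrophic factors stood at -0.25 (1.52e-06, 0.230), later activity-response genes at -0.28 (7.27e-06, 0.417). Inhibitory neuron markers stood at -0.24 (1.58e-05, 0.171), presynaptic release genes at -0.13 (3.49e-05, 0.230). Potassium and HCN channels stood at -0.12 (0.000345, 0.230), oxidative phosphorylation genes at -0.10 (0.000681, 0.486). Cytosolic ribosomal proteins stood at -0.071 (0.000906, 0.569), rapid activity-response genes at -0.22 (0.00679, 0.483). GABA receptors and inhibitory synapse genes stood at -0.15 (0.00679, 0.377), NMDA, kainate and metabotropic glutamate receptors at -0.11 (0.0172, 0.230). Averages of the genes fixed in advance did not pass. Fos stood at -0.44 ± 0.57, Npas4 at -1.14 ± 1.04 and Arc at -0.94 ± 0.64. Bdnf stood at -0.75 ± 0.71, Homer1 at -0.26 ± 0.29 and Nptx2 at -0.25 ± 0.18. Gria1 stood at -0.15 ± 0.13 and Gria2 at -0.084 ± 0.13. No gene passed in edgeR (smallest adjusted p = 0.192), with 789 genes at an unadjusted p under 0.05, 495 higher and 294 lower. Limma-voom called 0, but DESeq2 called 13 (7 higher, 6 lower) and edgeR without a low-count filter called 16 (11 higher, 5 lower), 9 of them shared. Once refitted without HH replicate 1, the later (adjusted p = 0.351), glutamate receptor (0.364) and GABA receptor (0.331) lists no longer passed and the rapid (0.631) list turned direction. Once refitted without HT replicate 1, the ribosomal (0.259) list no longer passed. Once refitted without HT replicate 2, the rapid (0.137), glutamate receptor (0.0569) and GABA receptor (0.198) lists no longer passed. Once refitted without TH replicate 1, the ribosomal (0.710) and oxidative phosphorylation (0.300) lists no longer passed. Once refitted without TH replicate 2, the glutamate receptor (0.0982), GABA receptor (0.117) and astrocyte (0.0982) lists no longer passed. Once refitted without TT replicate 2, the glutamate receptor (0.0582) list no longer passed. Once refitted without HH replicate 1 and HT replicate 1 together, the rapid (0.445), glutamate receptor (0.200) and ribosomal (0.237) lists no longer passed. With both of these left out, HH and HT being lone libraries assumed to vary like TH and TT, the lower lists that passed included later (0.00997) and GABA receptor (0.0126). Without HH replicate 2, 7 genes passed, all lower. In addition, 1 gene passed without HH replicate 1 (Ltbp1, named after its values were seen) or TH replicate 2 (Pole2).

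Whether history altered the response was tested by the interaction, and by setting the responses of HT against HH and of TT against TH side by side, which share no library. Across the 11372 genes their log2 changes had a Pearson correlation of 0.251 and a Spearman correlation of 0.240, with the same sign in 57.7% of genes. This is a description across genes, which are not independent replicates. Among the 9 ways of pairing the libraries within each history, the real one gave the largest correlation in size (0.253 from plain log2 means, the next being 0.115), and 9 ways are too few for a share under 0.05. The correlation was 0.0356 without HH replicate 2 and 0.149 without TH replicate 1.

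**Figure D3:**
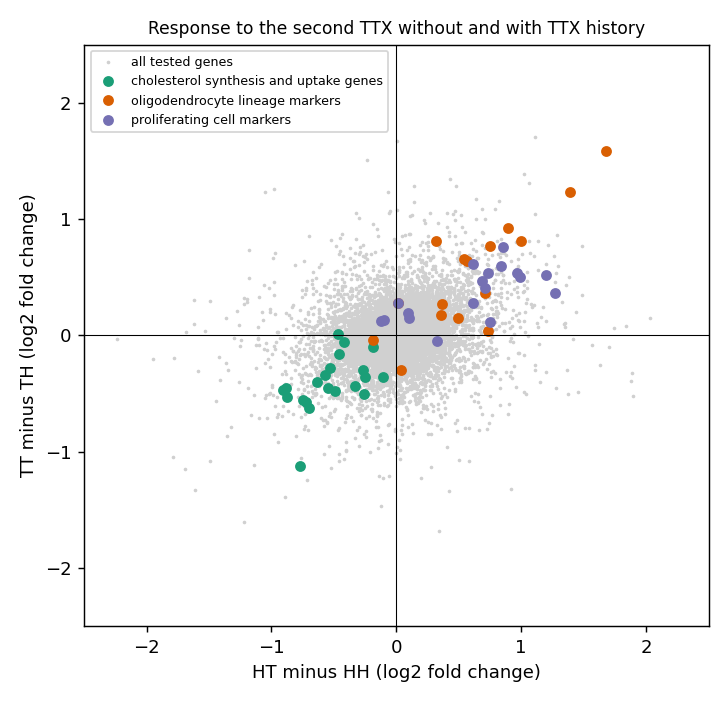
Log2 fold change of each tested gene after the second TTX without history (HT minus HH, x axis) and with TTX history (TT minus TH, y axis), with members of 3 gene lists coloured and 3 genes beyond the axes not drawn. All 21 cholesterol genes lie left of 0 and 20 lie below 0.

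No gene passed the interaction in edgeR (smallest adjusted p = 1.00), with 186 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Genes of smallest p were Tdrd5 (3.41 ± 0.72), Paqr5 (0.82 ± 0.20), Cspg4 (-0.69 ± 0.17), Unc119b (-1.07 ± 0.27) and E230034O05Rik (-1.45 ± 0.41), whose symbol has none of the prefixes left out as placeholders. Cspg4 passed when adjusted over the list alone (adjusted p = 0.0307, edgeR), its response being 0.73 ± 0.12 without history and 0.041 ± 0.12 with it. The cholesterol, oligodendrocyte lineage and proliferating lists did not pass (camera adjusted p = 0.194, 0.194 and 0.0785). A p above the threshold does not show that the responses were alike. Above 0 were the later activity-response genes (median 0.28, camera adjusted p = 0.00518, adjusted p = 0.865 with an estimated correlation), with Nfil3 at 1.04 ± 0.58. So were cytosolic ribosomal proteins (median 0.13, camera adjusted p = 0.0453, adjusted p = 0.865 with an estimated correlation). Interaction terms of the genes fixed in advance did not pass. Fos stood at 1.5 ± 1.14, Npas4 at 2.21 ± 2.07 and Arc at 1.28 ± 1.28. Bdnf stood at 1.57 ± 1.43, Homer1 at 0.61 ± 0.59 and Nptx2 at 0.51 ± 0.37. Gria1 stood at 0.10 ± 0.25 and Gria2 at 0.32 ± 0.27. When refitted without HH replicate 1, the later (adjusted p = 0.542) list turned direction. When refitted without HH replicate 2, the ribosomal (0.137) list no longer passed. When refitted without HT replicate 1, the ribosomal (0.954) list turned direction. When refitted without HT replicate 2, the later (0.311) list no longer passed. When refitted without TH replicate 2, the later (0.540) list no longer passed and the ribosomal (0.540) list turned direction. When refitted without TT replicate 1, the later (0.130) list no longer passed. When refitted without TT replicate 2, the ribosomal (0.133) list no longer passed. When refitted without HH replicate 1 and HT replicate 1 together, the later (0.344) and ribosomal (0.981) lists no longer passed. Without HH replicate 2, 2 genes passed, Nr4a1 and Htr2a, and without TH replicate 2 Pole2 (named after their values were seen), while the number of lists ran from 0 to 11 with single libraries left out.

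The next comparison asks what remained of the first TTX after the 48 h washout and 4 h of vehicle (TH against HH). Later activity-response genes fell, with 35 of 36 below 0 and a median of -0.60 (camera adjusted p = 5.67e-14, adjusted p = 0.241 with an estimated correlation). Among them were the prohormone convertase gene Pcsk1 (-1.43 ± 0.38), Sik1 (-0.73 ± 0.26), Nfil3 (-1.15 ± 0.40) and Rgs2 (-1.14 ± 0.41). Rapid genes (median -0.58, camera adjusted p = 1.71e-05, adjusted p = 0.335 with an estimated correlation), with Egr2 at -1.53 ± 0.47 and Egr4 at -1.48 ± 0.67, fell too. ERK pathway feedback genes fell as well (median -0.54, camera adjusted p = 2.43e-05, adjusted p = 0.335 with an estimated correlation), with Etv1 at -0.54 ± 0.19, Dusp5 at -1.66 ± 0.67, Spry1 at -0.68 ± 0.38 and Spred2 at -0.88 ± 0.51. Without HH replicate 1 the later list kept its direction, but the rapid and ERK lists turned to higher. The level of the later list was 0.060 in HH replicate 2, against 0.020 in TH replicate 1 and -0.34 in TH replicate 2. Its fall without HH replicate 1 thus rested mainly on TH replicate 2. Oligodendrocyte lineage markers rose (13 of 16 above 0, median 0.41, camera adjusted p = 5.39e-06, adjusted p = 0.241 with an estimated correlation), with Cspg4 at 0.36 ± 0.12, Gpr17 at 0.82 ± 0.33 and Bcas1 at 0.99 ± 0.44, and passed without HH replicate 1 (6.31e-05).

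AMPA receptor subunits and partners, the receptors of fast excitation, fell slightly (median -0.084, camera adjusted p = 0.0345, adjusted p = 0.241 with an estimated correlation), with the auxiliary subunit gene Cacng3 at -0.64 ± 0.19 and Syndig1 at -0.78 ± 0.31. Potassium and HCN channels fell (median -0.20, camera adjusted p = 0.000130, adjusted p = 0.241 with an estimated correlation), with Kcnk2 at -0.53 ± 0.19 and Kcnip4 at -0.41 ± 0.18. Camera called 19 lists, 3 higher and 16 lower, none with an estimated correlation (smallest adjusted p = 0.241 with an estimated correlation). The rest of the lists called follow with median, camera adjusted p and adjusted p with an estimated correlation. Neuropeptides and secreted neurotrophic factors stood at -0.56 (2.83e-06, 0.241), cytosolic ribosomal proteins at -0.15 (3.14e-06, 0.445). Presynaptic release genes stood at -0.15 (0.000174, 0.241), GABA receptors and inhibitory synapse genes at -0.25 (0.000174, 0.241). Cholesterol synthesis and uptake genes stood at -0.23 (0.000216, 0.417), inhibitory neuron markers at -0.29 (0.00232, 0.241). Voltage-gated sodium channels and partners stood at -0.19 (0.00557, 0.299), NMDA, kainate and metabotropic glutamate receptors at -0.15 (0.00665, 0.241). Oxidative phosphorylation genes stood at -0.10 (0.0118, 0.632), postsynaptic density scaffolds and signalling at -0.080 (0.0147, 0.400). Proliferating cell markers stood at 0.18 (0.0147, 0.335), astrocyte markers at 0.18 (0.0147, 0.241). Genes named in work on synaptic scaling stood at -0.063 (0.0351, 0.271). No gene passed in edgeR (smallest adjusted p = 0.891), with 464 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The smallest p belonged to Tdrd5 (-2.78 ± 0.58), Unc119b (0.88 ± 0.20), the transcription factor gene Mitf (-0.56 ± 0.13), Tnfrsf19 (0.76 ± 0.18) and Rxrg (-0.80 ± 0.20). The genes fixed in advance did not pass here. Fos stood at -1.35 ± 0.78, Npas4 at -2.97 ± 1.28 and Arc at -2.02 ± 0.83. Bdnf stood at -2.24 ± 0.98, Homer1 at -0.79 ± 0.42 and Nptx2 at -0.61 ± 0.26. Gria1 stood at -0.026 ± 0.18 and Gria2 at -0.25 ± 0.19. Without HH replicate 2, 121 genes passed, 8 higher and 113 lower, 20 of them rapid, later or ERK list members, and without TH replicate 2 only Pole2. HT against HH uses the same HH libraries, so part of any likeness between these comparisons comes from shared controls. Leaving out HH replicate 1 ended the call of the synaptic scaling (adjusted p = 0.373), glutamate receptor (0.393), GABA receptor (0.101), postsynaptic density (0.373), sodium channel (0.131), cholesterol (0.388), inhibitory neuron (0.260) and proliferating cell (0.0657) lists and turned the direction of the rapid (0.801) and ERK (0.479) lists. Leaving out HH replicate 2 ended the call of the AMPA receptor (0.0953), oxidative phosphorylation (0.149), astrocyte (0.131) and proliferating cell (0.110) lists. Leaving out TH replicate 1 ended the call of the synaptic scaling (0.241), AMPA receptor (0.0821), glutamate receptor (0.0821), GABA receptor (0.0512), postsynaptic density (0.0723) and astrocyte (0.241) lists. Leaving out TH replicate 2 ended the call of the AMPA receptor (0.167), postsynaptic density (0.0662), neuropeptide (0.0754), ribosomal (0.922), inhibitory neuron (0.172) and proliferating cell (0.320) lists and turned the direction of the oxidative phosphorylation (0.298) list. Leaving out HH replicate 1 and HT replicate 1 together ended the call of the synaptic scaling (0.335), glutamate receptor (0.355), GABA receptor (0.123), postsynaptic density (0.344), sodium channel (0.128), cholesterol (0.355), oxidative phosphorylation (0.0505), astrocyte (0.0505), inhibitory neuron (0.298) and proliferating cell (0.0671) lists and turned the direction of the rapid (0.784) and ERK (0.355) lists.

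In cultures given the second TTX, those with a TTX history were compared with those without (TT against HT). Potassium and HCN channels fell (37 of 49 below 0, median -0.17, camera adjusted p = 0.000392, adjusted p = 0.501 with an estimated correlation), with Kcnc4 at -0.87 ± 0.25, Kcnv1 at -1.28 ± 0.48 and Kcnk1 at -0.42 ± 0.18. Oligodendrocyte lineage markers rose (12 of 16 above 0, median 0.49, camera adjusted p = 0.00120, adjusted p = 0.538 with an estimated correlation), with Enpp6 at 0.69 ± 0.20 and Ugt8 at 0.93 ± 0.37, but Cspg4 at -0.34 ± 0.12. The levels of this list were 0.15 and 0.058 in HT and 0.15 and 0.71 in TT, replicate 1 first, so that TT replicate 1 lay close to HT replicate 1 and the difference came from TT replicate 2. Potassium channel levels were 0.14 and -0.082 in HT and -0.093 and -0.21 in TT. Later activity-response genes fell (median -0.26, camera adjusted p = 0.000555, adjusted p = 0.623 with an estimated correlation), with Ptgs2 at -1.64 ± 0.74 and Rgs2 at -0.91 ± 0.44. Cholesterol genes did not pass (median -0.045, camera adjusted p = 0.0708). Camera called 11 lists, 1 higher and 10 lower, and none with an estimated correlation (smallest adjusted p = 0.501 with an estimated correlation). The remaining ones follow with median, camera adjusted p and adjusted p with an estimated correlation. Postsynaptic density scaffolds and signalling stood at -0.13 (0.00416, 0.538), presynaptic release genes at -0.11 (0.00801, 0.538). Excitatory neuron markers stood at -0.15 (0.00967, 0.501), ERK pathway feedback genes at -0.33 (0.0107, 0.625). Genes named in work on synaptic scaling stood at -0.10 (0.0159, 0.501), neuropeptides and secreted neurotrophic factors at -0.13 (0.0285, 0.623). GABA receptors and inhibitory synapse genes stood at -0.13 (0.0289, 0.623), calcium handling and calcium signalling at -0.069 (0.0289, 0.538). No gene passed in edgeR (smallest adjusted p = 1.00), with 267 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Slc2a2 (2.32 ± 0.47), Tcf7l2 (0.79 ± 0.21), Arg2 (0.97 ± 0.27), Tmprss5 (1.22 ± 0.34) and Paqr5 (0.50 ± 0.14) had the smallest p. Again no gene fixed in advance passed. Fos stood at 0.15 ± 0.83, Npas4 at -0.77 ± 1.53 and Arc at -0.74 ± 0.95. Bdnf stood at -0.67 ± 1.03, Homer1 at -0.18 ± 0.41 and Nptx2 at -0.094 ± 0.26. Gria1 stood at 0.075 ± 0.18 and Gria2 at 0.077 ± 0.19. None of the 11 lists kept its call without TT replicate 2, and 9 lost it without HT replicate 1. In fits without HT replicate 1, the later (adjusted p = 0.519), synaptic scaling (0.559), GABA receptor (0.945), postsynaptic density (0.903), presynaptic (0.519), potassium channel (0.519), calcium handling (0.600) and neuropeptide (0.519) lists no longer passed and the ERK (0.954) list turned direction. In fits without TT replicate 1, the synaptic scaling (0.0788) list no longer passed. In fits without TT replicate 2, the later (0.132), ERK (0.104), synaptic scaling (0.104), GABA receptor (0.274), postsynaptic density (0.104), presynaptic (0.597), potassium channel (0.104), calcium handling (0.618), neuropeptide (0.618), oligodendrocyte lineage (0.688) and excitatory neuron (0.558) lists no longer passed. In fits without HH replicate 1 and HT replicate 1 together, the later (0.613), synaptic scaling (0.584), GABA receptor (0.864), postsynaptic density (0.820), presynaptic (0.552), potassium channel (0.552), calcium handling (0.594) and neuropeptide (0.731) lists no longer passed and the ERK (0.820) list turned direction.

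Averaged over the second treatment, a TTX history went with lower later activity-response genes (median -0.47, camera adjusted p = 2.56e-13, adjusted p = 0.234 with an estimated correlation). It also went with lower potassium and HCN channels (median -0.20, camera adjusted p = 8.04e-07, adjusted p = 0.234 with an estimated correlation) and with higher oligodendrocyte lineage markers (median 0.38, camera adjusted p = 4.00e-07, adjusted p = 0.234 with an estimated correlation). Adjusted over the list alone, 4 oligodendrocyte lineage genes passed, Enpp6 and Gpr17 among them. The per-library level of the later list did not separate the 4 libraries with a history from the 4 without (difference -0.42, exact permutation p = 0.0857, n = 4 each). Nor did that of the potassium and HCN channels (difference -0.20, exact permutation p = 0.0857) or of the oligodendrocyte lineage list (difference 0.38, exact permutation p = 0.229). Camera called 18 lists, 2 higher and 16 lower, and none with an estimated correlation (smallest adjusted p = 0.234 with an estimated correlation). All others called follow with median, camera adjusted p and adjusted p with an estimated correlation. Neuropeptides and secreted neurotrophic factors stood at -0.27 (3.98e-06, 0.234), ERK pathway feedback genes at -0.47 (7.33e-06, 0.295). Presynaptic release genes stood at -0.13 (1.62e-05, 0.234), cytosolic ribosomal proteins at -0.13 (1.62e-05, 0.482). Rapid activity-response genes stood at -0.44 (4.56e-05, 0.310), GABA receptors and inhibitory synapse genes at -0.12 (8.15e-05, 0.234). Cholesterol synthesis and uptake genes stood at -0.17 (0.000254, 0.410), postsynaptic density scaffolds and signalling at -0.10 (0.000380, 0.267). Inhibitory neuron markers stood at -0.20 (0.00211, 0.234), genes named in work on synaptic scaling at -0.087 (0.00294, 0.234). Calcium handling and calcium signalling stood at -0.090 (0.0101, 0.239), AMPA receptor subunits and partners at -0.073 (0.0101, 0.234). Voltage-gated sodium channels and partners stood at -0.12 (0.0428, 0.372), excitatory neuron markers at -0.036 (0.0462, 0.239). Astrocyte markers stood at 0.11 (0.0477, 0.234). History averages of the genes fixed in advance did not pass. Fos stood at -0.60 ± 0.57, Npas4 at -1.87 ± 1.01 and Arc at -1.38 ± 0.63. Bdnf stood at -1.46 ± 0.71, Homer1 at -0.49 ± 0.29 and Nptx2 at -0.35 ± 0.18. Gria1 stood at 0.025 ± 0.13 and Gria2 at -0.085 ± 0.13. After leaving out HH replicate 1, the rapid (adjusted p = 0.0805), ERK (0.0805), sodium channel (0.138), cholesterol (0.0570), astrocyte (0.0805) and inhibitory neuron (0.0630) lists no longer passed. After leaving out HH replicate 2, the astrocyte (0.165) and excitatory neuron (0.217) lists no longer passed. After leaving out HT replicate 1, the postsynaptic density (0.0671), sodium channel (0.174), calcium handling (0.0626), cholesterol (0.0995) and astrocyte (0.0807) lists no longer passed. After leaving out HT replicate 2, the ribosomal (0.0933), astrocyte (0.0986) and excitatory neuron (0.0986) lists no longer passed. After leaving out TH replicate 1, the sodium channel (0.107), calcium handling (0.0526), astrocyte (0.226) and excitatory neuron (0.121) lists no longer passed. After leaving out TH replicate 2, the ribosomal (0.279) and excitatory neuron (0.0659) lists no longer passed. After leaving out TT replicate 1, the cholesterol (0.0993) and astrocyte (0.102) lists no longer passed. After leaving out TT replicate 2, the AMPA receptor (0.0570), sodium channel (0.283), calcium handling (0.130) and excitatory neuron (0.286) lists no longer passed. After leaving out HH replicate 1 and HT replicate 1 together, the rapid (0.934), synaptic scaling (0.246), GABA receptor (0.295), postsynaptic density (0.512), sodium channel (0.597), calcium handling (0.252), astrocyte (0.193) and inhibitory neuron (0.246) lists no longer passed and the ERK (0.514) and cholesterol (0.905) lists turned direction. The later, potassium channel and oligodendrocyte lineage lists kept their direction without HH replicate 1. The oligodendrocyte lineage level was 0.71 in TT replicate 2 against 0.15 in TT replicate 1, so that a part of its rise with history came from TT replicate 2. No gene passed in edgeR (smallest adjusted p = 0.814), with 654 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. In contrast, 100 genes passed without HH replicate 2 (11 higher, 89 lower) and 1, Pole2, without TH replicate 2.

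The lists that passed in none of the 7 comparisons are given here for the averaged second TTX, with the median log2 change and the camera adjusted p: microglia markers (0.087, 0.887), endothelial, mural and fibroblast markers (0.037, 0.140), voltage-gated calcium channels (-0.065, 0.0822), circadian clock genes (0.021, 0.887), enzymes of DNA methylation and histone modification (0.010, 0.887) and unfolded protein and stress response genes (-0.063, 0.887). Fry, which tests whether a list's genes move on balance in 1 direction, called 0 lists in each comparison. Its test for change in either direction called 1 list after the second TTX without history and 3 in the averaged second TTX.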

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

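The interaction tests were planned, while the 6 tests of what sets HH replicate 1 apart were chosen only after its values had been seen.

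The interaction, which tests the difference with history itself, called 2 gene lists at the preset correlation and 1 gene within its list. No list passed with an estimated correlation, and no gene passed over all genes tested. A difference with history is thus not established. Later activity-response genes had a camera adjusted p of 0.00518 for the interaction (median 0.28), and adjusted p = 0.865 with an estimated correlation. The direction turned without HH replicate 1 (adjusted p = 0.542). Cytosolic ribosomal proteins had a camera adjusted p of 0.0453 (median 0.13), and adjusted p = 0.865 with an estimated correlation. Their direction turned without HT replicate 1 (0.954) and without TH replicate 2 (0.540). Cspg4, a marker of oligodendrocyte progenitors, had an interaction of -0.69 ± 0.17 with an edgeR adjusted p of 0.0307 when adjusted over the list alone and 1.00 over all genes. Its value lay between -0.76 and -0.63 over the alternatives run.

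The high activity-response genes of HH replicate 1 bear on the first of these and on every comparison with HH. An exchange of HH replicate 2 with HT replicate 2, TT replicate 1 or TT replicate 2 would not give HH replicate 1 a match. Their highest median log2 position in the rapid, later and ERK lists was 0.0151 against 0.801 or more in HH replicate 1. These lists cannot exclude such an exchange, since both TH libraries, given vehicle second, also stood low (0.0792 and -0.160 for the rapid list). Over the 24 lists outside the activity-response and ERK lists, the sum of squares within groups was 77.7 as labelled. It was 106, 129 and 132 with HH replicate 2 exchanged with HT replicate 2, TT replicate 1 and TT replicate 2. With each of these exchanges 0 lists separated the libraries by second treatment, against 3 as labelled. This goes with the labels, but how far such sums vary by chance was not tested. An exchange with HT replicate 1 cannot be told apart from a difference between cultures: its position was 0.251 for the rapid list against 0.83 in HH replicate 1 and 0.639 against 0.92 for the ERK list, and the sum of squares within groups over the 24 other lists was smaller with the exchange (72.4) than as labelled (77.7), but 3 lists separated the libraries by second treatment as labelled and 0 with the exchange. Oligodendrocyte lineage levels were -0.50 and -0.47 in HH and 0.15 in HT replicate 1, and proliferating cell levels -0.36, -0.30 and 0.12, which goes with the labels, although these lists, fixed in advance, were singled out here because they separate as labelled, and in fits of 2 groups of 4 camera called 16 lists with the exchange against 14 as labelled while 481 against 802 genes had an unadjusted p under 0.05. A higher share of neurons was left undecided by a first test, in which the higher of the 2 neuron marker medians in HH replicate 1, that of the inhibitory markers, was 0.529. A part played by such a share cannot be told apart from activity. A further test was added because the first was undecided. In it the mean position of the 58 activity-response genes (1.02) lay above that of the 35 neuron markers (0.23, permutation p = 2.00e-05, genes counted as independent). The 35 pool inhibitory (0.42) and excitatory (0.034) markers, and the activity-response genes were tested because they had been seen to be high. This p thus does not decide on the share of neurons. A difference in firing between cultures stays open and was not tested, and the labels do not say whether HH replicate 1 and HT replicate 1 share a culture.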

How the results depend on the processing

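Leaving out HH replicate 1 and HT replicate 1 together was chosen after the data were seen, and all other alternatives were planned. Over all alternatives, 3361 recomputed values of single genes and lists kept their direction and side of the threshold, 236 kept the direction but no longer passed, 22 newly passed and 72 turned direction. Of the recomputed counts of calls and the correlation, 171 stayed within their bounds and 48 moved. Where a value changed, the cause was not tested. With 3489176 to 4959887 counts per library, Npas4 rested on as few as 7 counts in a library and Fos on 22, so that changes of such genes are poorly bounded.

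With an estimated correlation between genes, 0 lists passed in HT against HH, 0 in TT against TH, 0 in TH against HH, 0 in TT against HT, 0 in the interaction, 0 in the averaged second TTX and 0 in the averaged history. For the averaged second TTX, DESeq2 called 13 genes and edgeR without a low-count filter 16. Scaling by library size only gave 4 lists in the interaction and turned Gria1 in TH against HH to 0.064, as did upper quartile factors (7.0e-05). Nptx2 in TT against TH, near 0, turned to -0.0047 with DESeq2, -0.00050 with median of ratios, -0.0054 with upper quartile factors and -0.0020 in a fit of only those groups. Limma-voom called 0 genes in each comparison, as did edgeR. At an unadjusted p under 0.05, limma-voom gave 696 genes in HT against HH, against 738 in edgeR. The counts were 290 against 300 in TT against TH and 781 against 789 in the averaged second TTX.

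Replicate numbers did not pair the libraries: the correlation of deviations was 0.447 between HH and HT but between -0.0658 and 0.0867 for the other pairs of groups. With the replicate number as a block edgeR called 0 genes in each comparison, and 16 lists passed in HT against HH, 9 in TT against TH, 20 in TH against HH and 12 in TT against HT. Under the block 4 lists passed in the interaction, 19 in the averaged second TTX and 17 in the averaged history.

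Without HH replicate 1 and HT replicate 1, HH and HT being lone libraries assumed to vary like TH and TT, 11 lists passed in TT against TH, 8 in TH against HH, 3 in TT against HT, 0 in the interaction and 9 in the averaged history. The ERK list turned in HT against HH (adjusted p = 0.899), TH against HH (0.355), TT against HT (0.820) and the averaged history (0.514), as did the rapid list in TH against HH (0.784) and the cholesterol list in the averaged history (0.905). Genes that turned had log2 values of 0.17 for Fos and 0.12 for Homer1 in HT against HH, -0.0012 for Nptx2 in TT against TH. They were 0.50 for Fos, 0.081 for Homer1, 0.065 for Spry1 and 0.029 for Spred2 in TH against HH. In TT against HT they were 0.79 for Npas4, 0.33 for Bdnf, 0.17 for Nptx2 and -0.071 for Gria1, and in the interaction -0.18 for Arc and -0.091 for Homer1.

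With single libraries left out in turn, the lone library of a group being assumed to vary like the other groups, the number of genes passing in edgeR ran from 0 to 32 in HT against HH, 0 to 1 in TT against TH, 0 to 121 in TH against HH, 0 to 2 in the interaction, 0 to 7 in the averaged second TTX and 0 to 100 in the averaged history. The number of lists ran from 8 to 20 in HT against HH, 4 to 13 in TT against TH, 10 to 20 in TH against HH, 1 to 14 in TT against HT and 0 to 11 in the interaction. The correlation of both responses ran from 0.0356 to 0.301. Adjusted p of lists that turned ran from 3.67e-22 to 0.163 for the rapid list and 2.62e-10 to 0.999 for the ERK list in HT against HH, 6.48e-07 to 0.721 for the neuropeptide list in TT against TH, and 5.01e-25 to 0.801 for the rapid list, 2.63e-15 to 0.479 for the ERK list and 3.10e-08 to 0.298 for the oxidative phosphorylation list in TH against HH. They ran from 5.17e-06 to 0.954 for the ERK list in TT against HT, 9.96e-11 to 0.542 for the later list and 5.17e-10 to 0.954 for the ribosomal list in the interaction and 1.72e-15 to 0.631 for the rapid list in the averaged second TTX.

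Log2 changes of genes that turned ran from -2.02 to 0.67 for Fos, -3.80 to 0.59 for Npas4, -2.39 to 0.17 for Arc, -2.54 to 0.27 for Bdnf and -1.11 to 0.30 for Homer1 in HT against HH. In TT against TH they ran from -0.17 to 0.087 for Npas4, -0.85 to 0.38 for Arc, -0.35 to 0.47 for Bdnf, -0.12 to 0.22 for Homer1, -0.25 to 0.27 for Nptx2, -0.24 to 0.061 for Gria1 and -0.091 to 0.27 for Gria2. In TH against HH they ran from -2.18 to 0.50 for Fos, -1.33 to 0.081 for Homer1, -1.20 to 0.065 for Spry1, -1.44 to 0.028 for Spred2 and -0.19 to 0.12 for Gria1. In TT against HT they ran from -0.20 to 0.65 for Fos, -1.47 to 0.80 for Npas4, -1.24 to 0.33 for Bdnf, -0.32 to 0.18 for Nptx2, -0.067 to 0.23 for Gria1 and -0.049 to 0.22 for Gria2. Interaction terms ran from -0.36 to 2.33 for Fos, -0.62 to 3.77 for Npas4, -0.48 to 2.09 for Arc, -0.24 to 2.58 for Bdnf, -0.27 to 1.15 for Homer1 and -0.041 to 0.26 for Gria1. In HT against HH and the interaction, each of these but Gria1 turned without HH replicate 1.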

Other observations

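The DESeq2, unfiltered and left-out library fits and the 2 counts of genes past the threshold over other splits were planned, while the tests of cell makeup, the use of the fits without HH replicate 1 as tests of that library and the counts of lists and of unadjusted p over splits were chosen only after the results had been seen, as were the genes named.

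Averaged over history, 9 genes passed both in DESeq2 and in edgeR without a low-count filter, although none passed in the edgeR test with the filter. Higher after the second TTX, with log2 changes and adjusted p from DESeq2, were Ect2, a regulator of cell division (0.75, 0.0283), Tspan2 (0.72, 0.0219), Acss1 (0.59, 0.0489), Abtb2 (0.63, 0.0489) and Sh3bp4 (0.52, 0.0364). Lower were Myo16 (-0.67, 0.00201), the adrenergic receptor gene Adra1a (-0.77, 0.0120), Pcbp3 (-0.58, 0.0211) and Hmgcs1 (-0.67, 0.00883). Genes called by DESeq2 but not by edgeR without the filter included Tns3 (0.80, 0.00883), Ltbp1 (-1.06, 0.0114) and Vipr2 (-1.5, 0.0120). The smallest adjusted p in DESeq2, 1.99e-05, belonged to a further gene, not named here, which edgeR without the filter did not call either. Without the filter, edgeR calls also included the cell division genes Smc4 (0.66, 0.0255), Kif15 (0.67, 0.0313), Cenpf (0.72, 0.0412) and Tpx2 (0.67, 0.0477).

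Pole2, which encodes a subunit of DNA polymerase epsilon, had 4.70 CPM in TH replicate 1 and from 766 to 1271 CPM in the other 7 libraries. It was the only one of the 11372 tested genes with a library at least 3 log2 units from the nearest other.

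Higher oligodendrocyte lineage and proliferating cell markers after the second TTX were weighed against cell makeup. A lower share of neurons raising all other types alike would move astrocyte, microglia and vascular markers equally, but the oligodendrocyte lineage markers moved by 0.45 more (permutation p = 0.000190) and the proliferating cell markers by 0.35 more (permutation p = 0.000220), with genes counted as independent. Both lists were singled out because they rose in these libraries, and genes rather than libraries were permuted. These p thus cannot decide on cell makeup. HH replicate 1 alone would leave no call without it, but the adjusted p were then 2.27e-12 and 4.37e-11 at the preset correlation, though with all libraries neither passed (adjusted p = 0.147 for both with an estimated correlation). More cells of the oligodendrocyte lineage in the wells given TTX cannot be told apart from more transcription per cell, since 14 of 16 tested markers lay above 0 and cells were not counted, with Cspg4 between 67.5 and 120.4 CPM over the 8 libraries. A response to the second TTX itself stays open and was not tested apart from these.

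Lower cholesterol genes after the second TTX remained past the threshold without HH replicate 1 (adjusted p = 5.10e-16 at the preset correlation), which argues against that library as the whole cause of that call. With all libraries the list did not pass (adjusted p = 0.171 with an estimated correlation). If cholesterol genes followed the share of neurons, which was not tested, a lower share would lower excitatory neuron markers alike. The cholesterol list lay -0.38 from them on the log2 scale (permutation p = 0.000120, genes counted as independent). Inhibitory neuron markers lay lower (median -0.24), and the cholesterol list lay -0.20 from them (permutation p = 0.00546). The cholesterol list was singled out because it fell in these libraries, and genes rather than libraries were permuted. Neither p can thus decide on cell makeup. A direct effect of the second TTX stays open, untested.

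For genes past the threshold in edgeR the splits of the 8 libraries into 4 and 4 say nothing, because the real count was 0 for the second TTX and for history and so 35 of 35 and 35 of 35 splits gave as many, the highest other being 0. These splits were fitted as 2 groups of 4 libraries with no term for the other treatment, so the counts can differ from those of the 4-group fit (789 genes at an unadjusted p under 0.05 and 14 lists for the averaged second TTX, 654 and 18 for the averaged history). In the 2-group fits, at an unadjusted p under 0.05, there were 802 genes for the second TTX and 708 for history, which 8 and 10 of 35 splits reached, the highest being 1342. Chance was not excluded for the number of lists. In these 2-group fits 7 of 35 splits gave as many as the second TTX (14, highest other 20), and 4 of 35 as many as history (17, highest other 20).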
